A study of Mus musculus with 8 samples.

How the data were processed

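The series holds 4 samples immunoprecipitated for m6A and 4 input samples, from frozen brain of APP/PS1 and C57BL/6 mice. The immunoprecipitated samples were analysed here. The inputs were not analysed here, since no lists are assigned to them among the files used. Groups and sample numbers come from the sample titles. The ages and read lengths in the labels move together in steps of 1 between samples, and they were not used.

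Each of the 12 peak lists has 6 columns with a chromosome, start, end, peak name, score and strand. Per the labels' protocols, libraries were made with a directional kit from immunoprecipitated and input RNA and sequenced as 150 bp pairs. Per the submitters' processing notes, cutadapt 1.9.3, STAR and HISAT2 2.0.4 were used, with mm10 as the genome build, with no role given for any of them. The peak names in the deposited lists carry the prefix of the peak caller MACS. Its version, its threshold and the annotation that divided the peaks into RNA classes are not given in the sources used here. The lists are separate for each sample, so peaks were called per sample as far as the files show. The deposited score of each peak is the authors' own value. Its scale is not stated, its values pile up at 3100, and it was used to rank peaks within a list. In the stricter setting, and for regions that score at least 3100 in all 4 animals, it also filtered the lists at a common value, which assumes that scores of different lists are comparable. This was not tested. The number in the peak name rises along each chromosome, and the highest number of an animal was taken as the number of peaks called in it. A peak that appears in 2 lists of an animal has the same number and the same score, in all 1830 such cases, but the same interval in only 154, so the lists hold parts of called peaks. This shortens intervals to as little as 1 bp.

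From these lists the following was computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. Distinct intervals were counted per list. Peaks of the 4 animals that overlapped by at least 1 bp were merged into regions within an RNA class. A region or gene was assigned to a genotype when both of its animals had a peak there and neither animal of the other genotype had. Coordinates are given 1-based in mm10. Gene spans came from a table of RefSeq genes on the assembly GRCm38.p6, which shares the coordinates of mm10. A peak was assigned to a gene when exactly 1 protein-coding span, or, where there was none, exactly 1 lncRNA span lay under it. The table has no exons, so exonic, intronic and untranslated positions are not given. The lists do not name circRNAs, and a host gene is therefore a gene whose span holds the peak. No genome sequence was used here, so the planned share of peaks with the DRACH motif was not run.

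Group means were compared with exact permutation tests, two-sided, which cannot give less than 0.333 with 2 animals per genotype. Counts of genotype-specific regions were set beside those of the other 2 splits of the 4 animals, and pairs of animals were compared by the Jaccard index of covered length. Before the data were examined, 18 gene lists were fixed. Of their members, all but Gm26917 and 2900097C17Rik were in the gene table. For each list, membership was compared between the directions by Fisher's exact test with Benjamini-Hochberg adjustment, where at least 3 members were genotype-specific. The number of protein-coding members with a peak in all 4 animals was compared with 10000 random lists drawn from 20 bins of span length. Named genes followed a fixed rule. For circRNA these were the 10 genes per direction with the best mean rank over the 2 animals of the genotype and the 5 shared genes with the most peaks, and for the other classes 5 and 3. Every list member among the genotype-specific genes was added, as was App in every class, and ties were broken by alphabet. Some genes that this rule names are not reported here. Examples of shared list members were taken in order of the same rank, except that the values printed with them are peak numbers. The comparisons of strand and of chromosome parts were added after the lists were seen. The parts were the first 18 Mb of chromosomes 13, 14 and 15 and, on chromosomes 13 to 19, positions beyond the end of the human chromosome of the same number, known from background and taken at a whole Mb past that end. A further comparison used 130 to 140 Mb of chromosome 1 and 51 to 60 Mb of chromosome 9, positions that in the human chromosomes of the same number are heterochromatin without genes, known from background. These parts and the bounds of the test were set before any peak was counted there.

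Alternatives were a stricter threshold at the median score of the 4 lists of a class, lists cut to the length of the shortest, overlap of at least 50% of both peaks, every line counted, intervals merged within an animal, strand ignored between classes, and each animal left out. Random thinning to equal lengths, with 100 draws, was chosen after seeing the data, as was the count of genes that kept their call. The calculations were tested on simulated data. In lists simulated for the comparison of circRNA regions between genotypes, with 3600 regions and 200 planted per genotype, 200 of each were recovered with 0 false calls. The simulated lists were equally long, and every planted region had a peak in both animals of its genotype. This checks the counting only. It does not show how unequal list lengths or missed peaks affect the calls. The precision of all comparisons between genotypes is limited by the 2 animals per group and by the unknown read depth. Exact binomial intervals of shares of peaks cover counting error only.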

Results

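N6-methyladenosine (m6A) was mapped in brain RNA by immunoprecipitation with an m6A antibody followed by sequencing, in which stretches of RNA enriched by the antibody appear as peaks. The tissue was frozen mouse brain, with cortex, hippocampus and cerebellum named together. APP/PS1 mice, which carry a transgene of a mutant amyloid precursor protein among others and are a model of Alzheimer's disease, were compared with C57BL/6 mice as controls. There were 2 immunoprecipitated samples of each genotype, numbered 6 and 9 for APP/PS1 and 3 and 6 for C57BL/6. The labels give each sample its own number without stating that each is a separate mouse. The samples are called animals here, and any p-value of a comparison between animals measures only the spread between these 4 samples. Fisher's exact tests of gene lists count genes, which are not replicates, so their p-values cover the allocation of genes only. Each animal has 3 peak lists, for circular RNA (circRNA), mRNA and long noncoding RNA (lncRNA). The circRNA lists held 4896 and 3551 peaks in APP/PS1 animals 6 and 9, and 9509 and 5781 peaks in C57BL/6 animals 3 and 6. Read depth is unknown, because the lists give positions and a score per peak but no read counts. The running number in the peak names reached 80258 and 54009 in the APP/PS1 animals and 138802 and 87007 in the control animals, and this number differed 2.57 times between the animals. The score is the authors' own value. Its median in the circRNA lists was 863 and 1088 in the APP/PS1 animals and 182 and 506 in the control animals, and it is used below to rank peaks within a list and, where stated, to filter all lists at a common score.

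The series asks whether m6A on circRNA differs between the genotypes. The circRNA lists are described first, by the host genes that all 4 animals shared. Peaks fell in 3181 host genes, and 1284 of these had a peak in every animal. The host with the most peaks summed over the 4 animals was Snhg14, the long noncoding host transcript of a snoRNA cluster on chromosome 7, with 29 and 16 peaks in the APP/PS1 animals and 31 and 23 in the control animals. A230006K03Rik, a noncoding gene on the same chromosome, followed with a sum of 89 peaks. Syne1, which encodes a nuclear envelope spectrin-repeat protein, had 84 peaks, the synaptic scaffold gene Magi2 had 78, and Zeb1, which encodes a transcription factor, had 72. App, the mouse gene of the amyloid precursor protein, had 5 and 7 circRNA peaks in the APP/PS1 animals and 8 and 4 in the control animals. Of 8 App regions, 3 had a peak in all 4 animals, at 85015060 to 85015529, 85024657 to 85025689 and 85056324 to 85056526 on chromosome 16 of mm10.

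Genes of synapses were prominent among the shared hosts. Of 37 postsynaptic glutamate genes, 23 had circRNA peaks in all 4 animals, among them the AMPA receptor subunit gene Gria2 with 62 peaks over the 4 animals, the NMDA receptor subunit gene Grin2b with 34, Grm3 with 21 and the scaffold gene Homer1 with 18. Among random gene lists matched on the length of the gene span, the median was 9, and 95% of the lists lay between 4 and 14. Of 35 presynaptic genes, 20 were shared, against a random median of 8 and a range of 3 to 13. They included the active zone genes Rims2 with 68 peaks, Rims1 with 57 and Erc2 with 55, and the synaptic vesicle gene Sv2b with 24. Of 19 GABA genes, 10 were shared, against a random median of 4 and a range of 1 to 7. Examples were Gphn, the gene of the inhibitory scaffold gephyrin, with 40 peaks, and the receptor subunit genes Gabra4 with 16 and Gabrb2 with 4. Of 35 ion channel genes, 18 were shared, against 9 and a range of 5 to 15. The intracellular calcium channel gene Itpr1 had 46 peaks, the sodium channel genes Scn2a and Scn1a had 29 and 22, and the calcium channel gene Cacna1b had 21.

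Regulators of chromatin, ubiquitin transfer and m6A itself were also frequent hosts. Of 32 chromatin regulator genes, 20 had circRNA peaks in all 4 animals, against a random median of 6 and a range of 2 to 11, with the histone methyltransferase genes Nsd1 and Kmt2c at 32 peaks each, Ash1l at 24 and Setd2 at 19. Of 25 ubiquitin ligase genes, 15 were shared, against 5 and a range of 1 to 9, with Mycbp2 at 40 peaks, Herc1 at 38, Huwe1 at 31 and Fbxw7 at 10. Of 23 genes of the m6A machinery, 6 were shared, against 2 and a range of 0 to 4. They included the m6A reader genes Ythdf3 and Ythdf2 and the methyltransferase complex gene Zc3h13, which had 4, 5 and 12 peaks over the 4 animals. Of 19 known brain circRNA hosts, 15 were shared, and the 14 of these that are protein-coding compare with a random median of 4 and a range of 1 to 8. Examples were Fbxw7 and Hivep2, which had 65 peaks.

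The remaining lists with protein-coding members lay within the range of the random lists. Of 33 Alzheimer's disease genes, 4 had peaks in all 4 animals, namely App with 24 peaks, the sorting receptor gene Sorl1 with 16, Cd2ap with 9 and Mef2c with 8, against a random median of 3 and a range of 1 to 7. The count was 4 of 22 for PI3K and mTOR genes, including Pik3r1 and Foxo3, and 3 of 25 for autophagy and lysosome genes, namely Vps13a, Vps13b and Lamp2. Among cell type markers it was 4 of 16 for astrocytes, namely Prex2, Slc4a4, the glutamate transporter gene Slc1a2 and S100b, 2 of 18 for oligodendrocytes, namely Pdgfra and Qk, and 0 of 12 for endothelium. Of 23 markers of microglia, 0 had a peak in all 4 animals, within the random range of 0 to 3, and 0 had a peak in any animal. The cerebellum and forebrain markers gave 1 of 19, Itpr1, and 2 of 19, Cux1 and Arpp21. Of 24 brain lncRNA genes, 7 were shared, among them Meg3, Gas5, Rmst and Snhg14. In all, 8 of the 17 lists with protein-coding members lay above the range of 10000 random lists and 0 lay below it. A list whose range starts at 0 could not lie below it. This holds for the m6A machinery, PI3K and mTOR, autophagy and lysosome, and all lists of cell type and brain region markers. The random lists were matched on span length but not on expression, which the lists do not give. They were drawn from all protein-coding genes, whether or not these give circRNA. An excess therefore cannot tell m6A from the making of circRNA, least of all for the list chosen as known circRNA hosts.

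**Figure D1:**
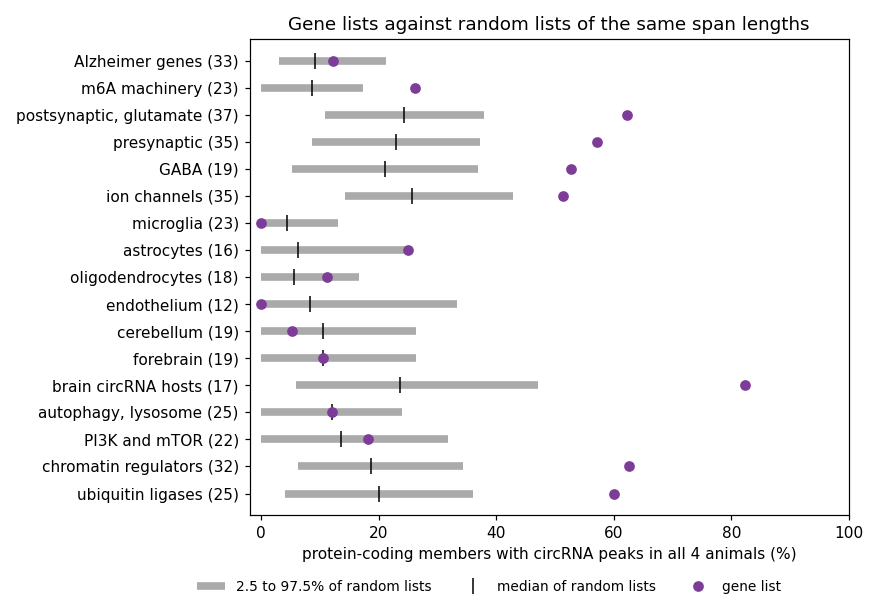
Share of each gene list's protein-coding members (percent, number of members in parentheses) with a circRNA peak in all 4 animals. Purple points are the lists, grey bars span the central 95% of 10000 random lists of the same span lengths, and black ticks are their medians; 8 of 17 lists lie to the right of their bar.

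The APP/PS1 animals had fewer circRNA peaks than the control animals. The mean was 4224 ± 951 (SD, n = 2) against 7645 ± 2636 (SD, n = 2), a ratio of 0.552, and both APP/PS1 lists were shorter than both control lists. The number of host genes was 1903 ± 225 against 2512 ± 405 (SD, n = 2 each), and the covered length was 1.44 ± 0.273 Mb against 2.45 ± 0.668 Mb (SD, n = 2 each). The exact two-sided permutation test gave p = 0.333 for the peak number, which is the smallest value that 2 against 2 allow. Measured as a share of the highest peak number of the animal, circRNA peaks were 6.10% and 6.57% in the APP/PS1 animals and 6.85% and 6.64% in the control animals, a ratio of the means of 0.939. Above a common stricter score threshold the ratio of the peak numbers was 0.988.

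**Figure D2:**
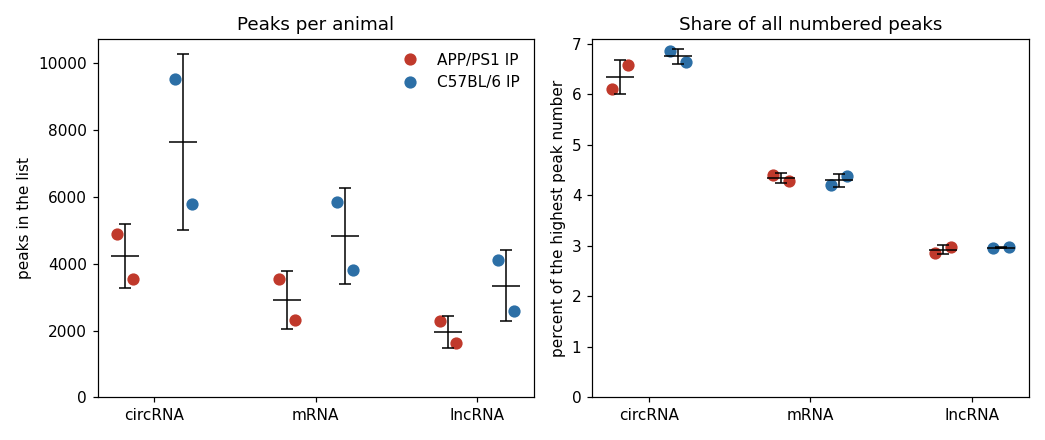
Left, number of peaks in each list; right, the same as a percent of the highest peak number of the animal. Points are animals (red, APP/PS1; blue, C57BL/6), and black bars are the mean and SD of 2 animals; the circRNA means are 4224 and 7645 on the left and 6.34% and 6.75% on the right.

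Host genes with a circRNA peak in both animals of a genotype and in neither animal of the other are described next. The APP/PS1 side held 7 genes. They were Frmpd4, which encodes a postsynaptic PSD-95-interacting protein, the exocyst gene Exoc1, the noncoding gene Gm32737, the bicarbonate transporter gene Slc4a8, Gps2, which encodes a subunit of a corepressor complex, Arhgdia, and Ptprn, which encodes a dense-core vesicle protein. In 6 of them the peaks of both APP/PS1 animals overlapped, such as Frmpd4 at 167856422 to 167857049 on chromosome X and Exoc1 at 76543304 to 76543724 on chromosome 5, and in Slc4a8 they lay at different positions. On a scale from near 0 for the strongest peak to 1 for the weakest, the mean ranks of the 7 genes began at 0.422, for Frmpd4. Those of Gps2, Arhgdia and Ptprn were 0.849, 0.921 and 0.939, near the weak end of the lists. The C57BL/6 side held 236 genes. Among the 10 with the strongest ranks were Dock4, a guanine nucleotide exchange factor gene with 10 peaks, the oxidoreductase gene Wwox with 3, the clathrin adaptor gene Hip1 with 7, Rapgef2, an exchange factor gene for Rap with 12, the phosphodiesterase gene Pde10a with 7, the amino acid transporter gene Slc43a2 with 3, the noncoding gene Gm19859 with 5, Zfyve1 with 3 and the centriolar satellite gene Pcm1 with 8. The mean ranks of these 10 genes ran from 0.0388 to 0.124. They rest on the best peak of a gene in each animal, wherever it lies. Overlapping peaks of both control animals lay, for example, at 40621221 to 40621304 on chromosome 12 in Dock4 and at 79174775 to 79175001 on chromosome 3 in Rapgef2. In control animals 3 and 6 these scored 3100 and 63.9 in Dock4, and 260 and 3100 in Rapgef2.

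Of the 236 genes on the C57BL/6 side, 11 belonged to a gene list, and of the 7 on the APP/PS1 side 0 did, too few genes for an excess on the C57BL/6 side to be tested. Synaptic members included Dlg4, the gene of the postsynaptic scaffold PSD-95, the presynaptic genes Syn2 and Ppfia2, and Rabgap1l. Others were the potassium channel gene Kcnq3, the mTOR complex gene Rictor, the ubiquitin ligase genes Nedd4l and Ubr4, and the transcription factor gene Etv1, a cerebellum marker. Only the presynaptic list had the 3 such members needed for a test, and Fisher's exact test, two-sided, of its 3 of 236 against 0 of 7 gave p = 1, adjusted p = 1, which an excess of 3 on the C57BL/6 side could not lower. The 33 Alzheimer's disease genes and the 23 genes of the m6A machinery had 0 members on either side. In Dlg4, Syn2, Rabgap1l, Rictor and Etv1 the peaks of the control animals lay at different positions. In Ppfia2, Kcnq3, Nedd4l and Ubr4 they overlapped.

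At the level of regions, 14432 merged circRNA regions were found, of which 1237 had a peak in all 4 animals and 9188 in 1 animal only. Regions with a peak in both APP/PS1 animals only numbered 139, and regions with a peak in both control animals only numbered 928. The total of 1067 compares with 988 and 693 for the other 2 ways of splitting the 4 animals into pairs. With the strongest 3551 peaks of each animal, the counts were 242 and 225, a total of 467 against 489 and 529 for the other splits, and the gene counts became 71 and 96. Of the 7 APP/PS1-only genes, 4 kept their call with equal list lengths, namely Frmpd4, Exoc1, Gm32737 and Slc4a8, and of the 236 C57BL/6-only genes 74 did. Above the stricter score threshold the same 4 and 59 kept it. Of the 11 list members on the C57BL/6 side 3 kept it under either setting, namely Nedd4l, Ppfia2 and Rabgap1l, so the call of the others, Dlg4 and Syn2 among them, was lost.

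**Figure D3:**
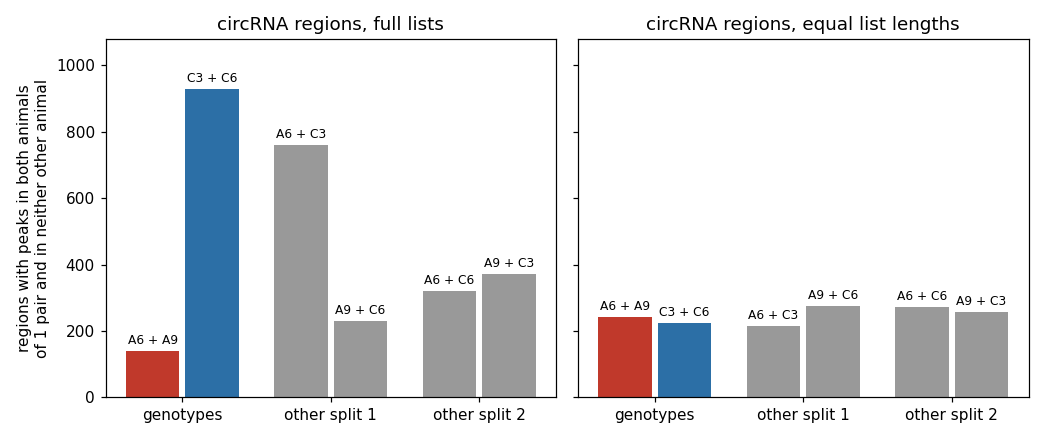
Number of merged circRNA regions with peaks in both animals of a pair and in neither other animal, for the genotypes (red, APP/PS1 animals A6 and A9; blue, C57BL/6 animals C3 and C6) and for the other splits (grey). With full lists the genotype bars are 139 and 928; with the strongest 3551 peaks of each animal they are 242 and 225.

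Pairs of animals were then compared by the circRNA peaks they shared. The mean Jaccard index, the shared length over the covered length of a pair, was 0.307 for the 2 pairs of the same genotype and 0.293 for the 4 other pairs, and the exact test over the 3 splits gave p = 0.667. Among single pairs, the highest index was 0.324, between APP/PS1 animal 6 and C57BL/6 animal 6. With equal list lengths the difference was -0.00351.

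The mRNA lists are reported by position, and a gene is named only because its span in mm10 holds the peak. Among spans with an mRNA peak in every animal, those of Ptprd, Cadm2 and Lrrc4c, genes of synaptic cell adhesion proteins, had the most peaks summed over the 4 animals, 70, 69 and 60. Cadm2 had more than Ptprd in both APP/PS1 animals and fewer in both control animals. In App there were 3 and 2 mRNA peaks in the APP/PS1 animals and 4 and 3 in the control animals. The App region with an mRNA peak in every animal, 85015476 to 85015529, has the same scores as the circRNA region at 85015060 to 85015529. In total the mRNA lists held 3539 and 2308 peaks in the APP/PS1 animals and 5836 and 3814 in the control animals, a ratio of the means of 0.606 (exact permutation p = 0.333, two-sided, n = 2 each). As a share of the highest peak number the ratio was 1.01, and above the stricter threshold the ratio of the peak numbers was 0.997. Spans with a peak in both APP/PS1 animals only numbered 40, led by Blmh, Cyhr1, Fbxo30, Sned1 and Ikbip, and included 1 list member, the ubiquitin ligase gene Hectd2. Spans with a peak in both control animals only numbered 269, led by Sertad2, the receptor kinase gene Alk, the calcium-binding protein gene Cabp1, Vps13a and Itpk1. The 11 list members among them were Magi1, the sodium channel genes Scn8a and Scn3a, Hivep2, Cux1, Vps13a, Wipi2, Nedd4l, Crebbp, Gabrb1 and the Alzheimer's disease gene Ptk2b. Of these, Hivep2, Cux1 and Vps13a had circRNA peaks in all 4 animals, so their control-only call does not extend to the circRNA lists. No list had enough members for a test. The peaks of both animals of the genotype overlapped in Blmh, Cyhr1, Sertad2, Alk, Cabp1, Itpk1, Scn3a and Cux1. In the other named genotype-specific spans, Magi1, Scn8a and Vps13a among them, they lay at different positions. With equal list lengths 25 of the 40 and 95 of the 269 spans kept their call. Of the list members, 5 of 11 on the control side kept it, namely Magi1, Scn8a, Hivep2, Vps13a and Wipi2, and Hectd2 lost it. Above the stricter threshold 23 and 70 spans kept it, and of the list members only Magi1, Scn8a and Vps13a did. The counts with equal list lengths were 89 and 121 spans, and the regions, 140 against 451 in full, were 148 against 126.

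The lncRNA lists gave a similar account. Nkain2, Ptprd and Robo2 held 42, 39 and 34 lncRNA peaks summed over the 4 animals, and App held 4 and 3 in the APP/PS1 animals and 4 and 3 in the control animals. The lncRNA region of App at 85120520 to 85120772 has the same scores as its circRNA region at 85120530 to 85120697. The lncRNA lists had 2297 and 1613 peaks in the APP/PS1 animals and 4101 and 2585 in the control animals, a ratio of the means of 0.585 (exact permutation p = 0.333, two-sided, n = 2 each). As a share of the highest peak number the ratio was 0.987, and above the stricter threshold the ratio of the peak numbers was 0.989. Of 34 spans on the APP/PS1 side, the first were Rorb, Smim14, Mctp1, Maml2 and Gm5165, and the list member was Myrf, the gene of an oligodendrocyte transcription factor. Of 251 spans on the control side, the first were Usp33, Exoc4, Trim67, C130026L21Rik and Col4a2. Its 16 list members were the Alzheimer's disease genes Sorl1 and Abca7, the m6A genes Fto and Zc3h13, the microglial gene Itgam, the astrocyte gene Prex2, the oligodendrocyte gene Qk, Herc1, Ubr3, Rmst, Uvrag, Ulk2, Gabra4, Dlgap2, Rims2 and Zfp609. The Usp33 peaks of the control animals, at 152368149 to 152368236 on chromosome 3, meet a circRNA region at 152368236 to 152368650. That circRNA region scored at least 3100 in all 4 animals, so the control-only call of Usp33 does not extend to the circRNA lists. The same limit holds for Sorl1, Zc3h13, Prex2, Qk, Herc1, Rmst, Gabra4, Rims2 and Zfp609, which had circRNA peaks in all 4 animals. Only the list of brain circRNA hosts, with Rmst, Rims2 and Zfp609, had enough members for a test, and Fisher's exact test of 3 of 251 against 0 of 34 gave p = 1, adjusted p = 1, with the same limit. Of the 34 and 251 spans, 24 and 71 kept their call with equal list lengths. Of the list members, Myrf kept it, and on the control side 4 of 16 did, namely Zc3h13, Prex2, Herc1 and Rmst, while the Alzheimer's disease genes and Fto lost it. Above the stricter threshold 15 and 48 spans kept it, and Rmst lost it too. Among the spans named on the APP/PS1 side, the peaks of both animals overlapped only in Gm5165. On the control side they lay at different positions in Exoc4, Trim67, Uvrag, Fto, Dlgap2, Ubr3, Rims2 and Zfp609, and overlapped in the other named spans. The counts with equal list lengths were 73 and 86 spans, and the regions, 84 against 357 in full, were 109 against 86.

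The mRNA and lncRNA lists differed from the circRNA lists in where their peaks lay. In genes whose circRNA peaks all lay on the same strand, 48.7% of 6066 mRNA peaks (95% exact interval 47.4% to 49.9%) and 51.8% of 4023 lncRNA peaks (50.2% to 53.3%) were on that strand. On chromosome 18 the last mRNA peak ended at 77.8 Mb, the last lncRNA peak at 77.9 Mb and the last circRNA peak at 89.0 Mb. On chromosomes 13, 14 and 15 the first 18 Mb held 380 circRNA peaks and 0 mRNA or lncRNA peaks. Of the circRNA peaks, 3.09% ± 0.191 in the APP/PS1 animals and 3.11% ± 0.230 in the control animals (SD, n = 2 each) were overlapped on the same strand by an mRNA or lncRNA peak of the same animal, and the exact permutation test gave p = 1. Linear and circular transcripts of a gene share exons, so reads of either can give peaks in both kinds of list. With mRNA and lncRNA peaks on either strand, this low overlap does not show that circRNA peaks are separate from linear RNA.

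**Figure D4:**
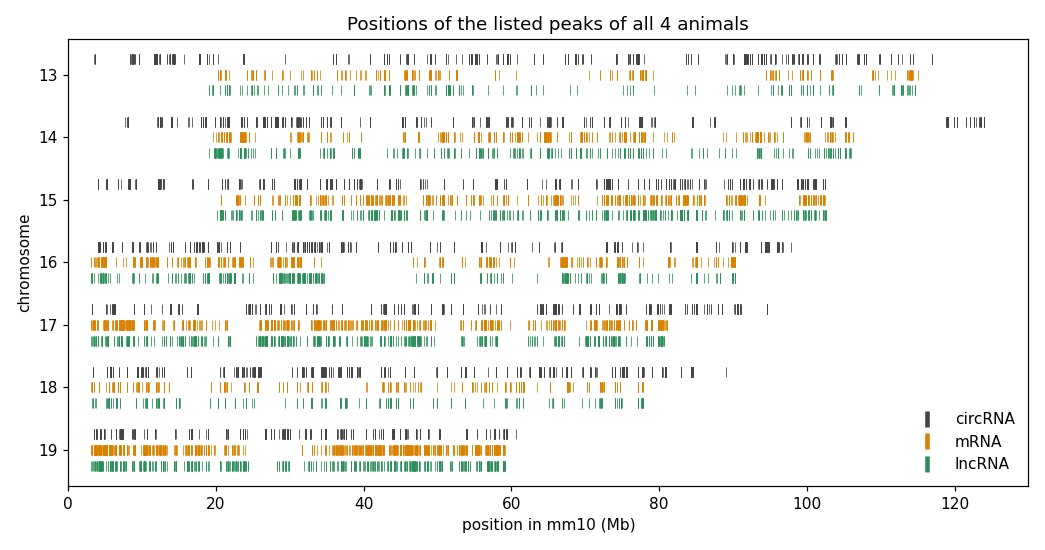
Positions (Mb, mm10) of the peaks of all 4 animals on chromosomes 13 to 19, each tick a peak, with circRNA in grey, mRNA in orange and lncRNA in green. The first 18 Mb of chromosomes 13, 14 and 15 hold 380 circRNA peaks and 0 of the other classes, and on chromosome 18 the mRNA peaks end at 77.8 Mb and the circRNA peaks at 89.0 Mb.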

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

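The tests of explanations in this part were chosen after the results were seen, apart from the exact permutation test, the equal list lengths and the other splits of the animals, which were planned, and the test on parts of chromosomes 1 and 9, which was written before its peaks were counted. Most called peaks lay in none of the lists used here. Going by the highest peak number, 87.1% and 86.6% of the called peaks of APP/PS1 animals 6 and 9, and 86.5% of those of both C57BL/6 animal 3 and C57BL/6 animal 6, appear in none of the circRNA, mRNA and lncRNA lists. They stand out as signal outside the data that were compared, and their positions were not analysed here.

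The first pattern weighed is the smaller number of circRNA peaks in the APP/PS1 animals. A smaller number of peaks called over the whole genome is a candidate explanation, because the circRNA share of the highest peak number had a ratio of 0.939 between the genotypes, against 0.552 for the peak numbers. Whether that smaller number came from read depth, from the antibody step or from the animals stays open, as read depth is unknown. The APP/PS1 genotype cannot be told apart from chance by the exact permutation test, whose p of 0.333 is the smallest that 2 against 2 can give.

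The second pattern is the excess of circRNA regions found in both control animals only, 928 against 139. The longer peak lists of the control animals are a candidate explanation. With equal list lengths the ratio of APP/PS1-only to control-only regions was 1.08, with random thinning it was 1.74, and with the full lists it was 0.150. Both settings by construction remove more peaks from the longer control lists, so they lower the control-only count whatever its cause. These ratios therefore cannot tell list length from another cause. An effect of the genotype cannot be told apart here, since 4 animals make only 3 splits, too few for a share under 0.05. The genotype split was the 1 split of the 3 that reached 1067 regions, and the highest other split gave 988. With equal list lengths it was the lowest of the 3, at 467 against 489 and 529, and with the stricter threshold too, at 380 against 423 and 449, while with random thinning it gave 688 against 688 and 570.

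The third pattern is that the mRNA and lncRNA lists leave whole chromosome parts empty. Mouse gene models in mm10 coordinates would place mRNA peaks on the strand of the gene, and the share on the strand of the circRNA peaks was 48.7%. For the lncRNA lists the test used other chromosome parts than those that showed the pattern, 130 to 140 Mb of chromosome 1 and 51 to 60 Mb of chromosome 9. A count of 0 among 10596 lncRNA peaks allows a share of up to 0.0348% there (exact 95% interval), while 0.935% of the mouse RefSeq lncRNA genes lie there. Both values argue against such models. A hypothesis that remains is that these lists were divided using gene models with human chromosome coordinates. It arose from the empty parts of chromosomes 13 to 19. In the parts of chromosomes 1 and 9, which in the human chromosomes of the same number are heterochromatin without genes, 0 of 26093 mRNA and lncRNA peaks lay, against 291 of 23737 circRNA peaks (1.23%). No biological explanation was tested, since no group in the design predicts empty chromosome parts.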

How the results depend on the processing

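All alternatives here were chosen before the data were examined, except random thinning. The lower peak number of the APP/PS1 animals kept its direction in all 3 classes above the stricter score threshold. There the ratios came close to 1, at 0.988, 0.997 and 0.989 for circRNA, mRNA and lncRNA. Counting every line and merging intervals within an animal gave the same ratios as the main setting, so they tested nothing further. Leaving out an animal could not turn the direction, since in every class both APP/PS1 lists were shorter than both control lists. Equal list lengths and random thinning set the peak numbers, and the overlap setting leaves them as they are, so these give no value for it. With full lists, equal list lengths and the stricter threshold, only 2, 1 and 2 gene list tests had enough members, and 0 of them passed p = 0.05 by Fisher's exact test before or after adjustment, with a lowest unadjusted p of 0.313. With full lists all members tested lay on the control side, where so few cannot pass, so the lack of a pass says nothing about stability. The ratio of the overlap between RNA classes stayed between 0.974 and 0.995. Overlap of at least 50% of both peaks kept all region counts within 1.5 times.

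The excess of control-only regions turned around with equal list lengths, the stricter threshold and random thinning. Equal list lengths and random thinning by construction remove more peaks from the longer lists. The stricter threshold does so only because scores were lower there, with circRNA medians of 182 and 506 against 863 and 1088, and for it the cause was not tested. APP/PS1-only regions against control-only regions were 242 against 225, 200 against 180 and 437 against 251 for circRNA, 148 against 126, 122 against 102 and 249 against 134 for mRNA, and 109 against 86, 76 against 71 and 181 against 99.6 for lncRNA, in that order of settings. For genes the counts were 71 against 96, 77 against 98 and 108 against 114 for circRNA, 89 against 121, 93 against 104 and 116 against 120 for mRNA, and 73 against 86, 63 against 70 and 94.6 against 92.9 for lncRNA, the last of which turned around. The difference in Jaccard index between pairs of the same and of different genotypes turned to -0.00351 with equal list lengths and -0.00105 with the stricter threshold for circRNA, to -0.00326 and -0.00183 for mRNA, and, with the stricter threshold, to -0.000959 for lncRNA; the cause was not tested.

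Leaving out an animal loosens the call, since a genotype is then represented by 1 animal, and gives values with no test. Without APP/PS1 animals 6 and 9 and C57BL/6 animals 3 and 6, in that order, APP/PS1-only circRNA regions numbered 989, 1550, 326 and 272, and control-only regions 1546, 1243, 2852 and 5988. The circRNA genes were 67, 82, 100 and 44, and 561, 375, 352 and 680. For mRNA, APP/PS1-only regions ranged from 260 to 1833 and control-only regions from 607 to 4149, and genes from 82 to 294 and from 411 to 988. For lncRNA the ranges were 166 to 1108 and 462 to 2886 for regions, and 64 to 270 and 359 to 966 for genes. The difference in Jaccard index ranged from -0.0108 to 0.0435 for circRNA, -0.00231 to 0.0272 for mRNA and -0.00194 to 0.0362 for lncRNA, the highest each time without C57BL/6 animal 6. The peak number ratio ranged from 0.444 to 0.731 for circRNA.

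No paired analysis was possible because the immunoprecipitated groups share only the number 6 and the input samples have no lists used here. The motif shares were not run, for lack of a genome sequence. Depth limits all comparisons in an unknown way, as the lists hold no read counts.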

Other observations

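The circRNA regions that were strongest in every animal were examined as a set, chosen after their values were seen. In 168 regions all 4 animals had a score of at least 3100, where the scores pile up, which is 13.6% of the 1237 regions with a peak in all 4. They had a median width of 791 bp and lay in 156 genes, 29 of which belong to a fixed gene list. The widest among list members were in Ash1l, 4558 bp at 88981233 to 88985790 on chromosome 3, and in Setd2, 4286 bp at 110547209 to 110551494 on chromosome 9, both genes of histone methyltransferases. Known brain circRNA hosts gave 7 genes, including Rims2, Homer1, Tulp4, Slc8a1 and Zfp609, and the list of m6A machinery gave Ythdf3 and Zc3h13. Ube3a, the ubiquitin ligase gene affected in Angelman syndrome, held 2 such regions, at 59275768 to 59277014 and 59300081 to 59301514 on chromosome 7. Syt1, the synaptic vesicle calcium sensor gene, and Scn2a also held 2 each. The noncoding gene Meg3 had a region of 177 bp at 109559928 to 109560104 on chromosome 12. Markers of microglia, astrocytes, endothelium, cerebellum and forebrain had 0 members in this set, as had the autophagy and lysosome genes. The set was not compared with random lists, so these counts have no expected value beside them.

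By the gene spans that hold the peaks, 2 of the 17 gene lists with protein-coding members lay above the range of the length-matched random lists in the mRNA lists, and in the lncRNA lists 5 did, against 8 in the circRNA lists. The postsynaptic glutamate genes were above it in all 3 classes, with 23, 14 and 11 of 37 members holding peaks in all 4 animals. The 3 classes are not independent, as in 1830 cases a called peak of an animal appears in 2 lists. Only 48.7% of the mRNA and 51.8% of the lncRNA peaks lay on the strand of the gene's circRNA peaks. The random lists were not matched on expression or, for circRNA, on whether a gene gives circRNA.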
